A study of Mus musculus with 15 samples.

How the data were processed

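Gene expression was measured on arrays in 4T1 cells, a metastatic mammary carcinoma line from the mouse. The 34760 probe sets were read on 15 arrays, 3 for each of 5 cell lines. These were parental cells, cells depleted of the transcription factor Twist1 (Tw1KD), and Tw1KD cells that carried wild-type Twist1, Twist1 S42A or Twist1 S42D. Groups were taken from the sample titles. The genotype label of the S42D samples names both substitutions, so their identity rests on the title alone. Per the labels' protocols, cells were grown to 70% confluency in DMEM with 4 µg/ml puromycin and 800 µg/ml G418. Whether parental cells received these drugs is not stated separately, and a difference in them would enter every comparison with parental cells. RNA came from a Qiagen RNeasy kit, and 100 ng of it went through an Ambion whole-transcript kit with biotin as the label. The sources used here do not give how Twist1 was depleted or the constructs introduced.

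The deposited values were log2 intensities, 1 per probe set, as summarised by the authors. The unit was read from the values themselves. Per the submitters' processing notes, R 2.10.0 and the affy package were used, with no role stated. Background correction, normalization and the summary over probes are not given. The values were not centred per gene, and the quartiles of all arrays lay close together, as after a scaling between arrays. The array medians (log2) were 6.68, 6.72 and 6.70 in parental cells, 6.63, 6.71 and 6.66 in Tw1KD cells, 6.58, 6.57 and 6.59 in the wild-type Twist1 line, 6.65, 6.60 and 6.58 in the S42A line and 6.61, 6.67 and 6.59 in the S42D line. Scaling of this kind removes any change common to all transcripts, so each difference is relative to the other transcripts of the same array. Signals near the array background compress large fold changes, and the depth behind a value is not known for arrays; the number of arrays limits the precision.

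Of the probe sets, 21640 carried 1 gene symbol, 1321 carried several and 11799 carried none. Symbols were brought up to date by gene number against the mouse gene table of assembly GRCm38.p6, which matched 21553 probe sets. Probe positions were not analysed here, so genes carry no coordinates. A gene was represented by its brightest probe set among those with 1 symbol, which gave 19937 genes. Of these, 954 had more than 1 probe set. Probe sets with several symbols or none were left out of the main test. No filter on dim probe sets was applied.

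All 15 arrays were fitted in 1 model with a mean per line, in limma 3.58.1 under R 4.3.3. Genes were called by limma's moderated test with Benjamini-Hochberg adjustment, 2-sided, at an adjusted p under 0.05 in each of 10 comparisons. Of these, 7 were main comparisons (each derived line against the line it came from, and the 3 re-expressing lines against each other) and 3 were secondary (each re-expressing line against parental cells). Errors after ± are standard errors for differences and standard deviations for levels, with n = 3 arrays per line throughout. The labels do not say whether replicates were separate cultures, so every p-value measures only the spread between these samples. The median standard deviation of a gene within a line was 0.086 log2, and some genes had the same value on all 3 arrays of a line.

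The 21 gene lists were written before the data were examined, with the comparisons, tests and alternatives. They hold 618 entries, of which 579 were measured. The 17 primary lists are epithelial junctions and keratins, mesenchymal markers, EMT transcription factors, reported Twist1 targets, TGF-beta pathway components, TGF-beta response genes, PI3K-Akt pathway components, matrix proteases and inhibitors, cytokines and chemokines, interferon response, cell cycle, p53 response, hypoxia and glycolysis, cholesterol synthesis, unfolded protein and amino acid stress, stem and mammary lineage markers and adhesion and integrins. The 4 others are fibroblast markers, macrophage and leukocyte markers, endothelial markers and housekeeping genes. Each list was compared with the remaining genes by camera with a preset correlation of 0.01, adjusted over the primary lists of a comparison, and over the 4 other lists among themselves. Camera with an estimated correlation and fry were run beside it. Member counts are given over all genes and adjusted within the list.

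Genes are named by a rule that preceded the data. It takes genes with an adjusted p under 0.05 whose 3 arrays do not overlap with those of the other line. The 10 largest rises and falls are taken for the first 2 main comparisons, 6 for the other main ones and 3 for the secondary ones. To these it adds up to 2 called members per list and direction in each main comparison, and Twist1, Tgfb2, Cdh1, Cdh2, Vim, Fn1, Snai2 and Pdgfra whatever their result. Predicted and clone-named gene models (Gm, Rik, LOC and models with sequence-record names) were passed over in the naming and kept in the counts. Where 5 or fewer members of a list went one way or were not called, all are named, and those beyond the rule were chosen after their values were seen.

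A gene was counted as reversed when it was called in Tw1KD against parental cells and called with the opposite sign in a re-expressing line against Tw1KD. Both comparisons use the same Tw1KD arrays, which favours opposite signs. Each overlap was therefore set beside the count from independent lists of the same sizes and beside 30 simulations of an unchanged line measured against the same arrays. No overlap free of shared arrays was computed. For the order of genes along chromosomes, 13330 genes with a mean of at least 6 log2 were used. Log2 differences of genes 20 places apart were correlated and compared with 100 shuffled orders. A neighbour correction, added after the data were seen, subtracted on each array the running median of 50 neighbours.

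Alternatives were quantile normalization, median centring of each array, leaving out the dimmest 0.333 of genes by mean, a trended and robust variance, array weights, fits on the 2 lines alone, the replicate number as a block, all probe sets, the mean of a gene's probe sets, a 1.5-fold minimum and leaving out each array in turn. The fit was tested on 19937 genes simulated from the Tw1KD and parental arrays. Of 50 genes shifted by 0.5 log2, 98% were recovered, and of those shifted by 1, 2 or 3 log2, 100%. Of genes left unchanged, 10 were called. Plots were drawn with matplotlib 3.10.9.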

Results

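Transcript levels were measured in 5 lines of 4T1 mouse mammary carcinoma cells, with 3 arrays per line and 34760 probe sets per array. Parental cells served as the control. Twist1, a basic helix-loop-helix factor that drives epithelial-mesenchymal transition, was depleted in the Tw1KD line. The 3 other lines were Tw1KD cells with wild-type Twist1, with S42A or with S42D. Serine 42 is known as a site that protein kinase B (Akt) phosphorylates; alanine cannot be phosphorylated there and aspartate carries a charge like that of a phosphate. Correlations between arrays across genes were 0.997 to 0.999 within lines and 0.975 to 0.987 between lines. The 3 arrays per line limit the precision of every value, and the scaling method is unknown.

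Twist1 itself (probe set 10395320) had log2 values of 9.01, 9.03 and 9.07 in replicates 1 to 3 of parental cells and 7.47, 7.23 and 7.35 in Tw1KD cells. They were 8.35, 8.49 and 8.16 in the wild-type Twist1 line, 8.60, 8.71 and 8.80 in the S42A line and 9.07, 8.96 and 8.97 in the S42D line. Twist1 fell by 1.69 ± 0.080 log2 on depletion, a 3.22-fold change (adjusted p = 7.1e-10, n = 3). Against Tw1KD it rose by 0.99 ± 0.080 in the wild-type line, 1.36 ± 0.080 in the S42A line and 1.65 ± 0.080 in the S42D line. The re-expressing lines also differed among themselves, S42A by 0.37 ± 0.080 and S42D by 0.67 ± 0.080 from the wild-type line and S42D by 0.29 ± 0.080 from S42A. Against parental cells Twist1 stayed lower in the wild-type line (-0.70 ± 0.080) and in the S42A line (-0.33 ± 0.080), and was not called in the S42D line (-0.034 ± 0.080, adjusted p = 0.78). Whether this probe set reads the introduced transcripts is not known, so it is open whether its values include the Twist1 made from the constructs.

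**Figure D1:**
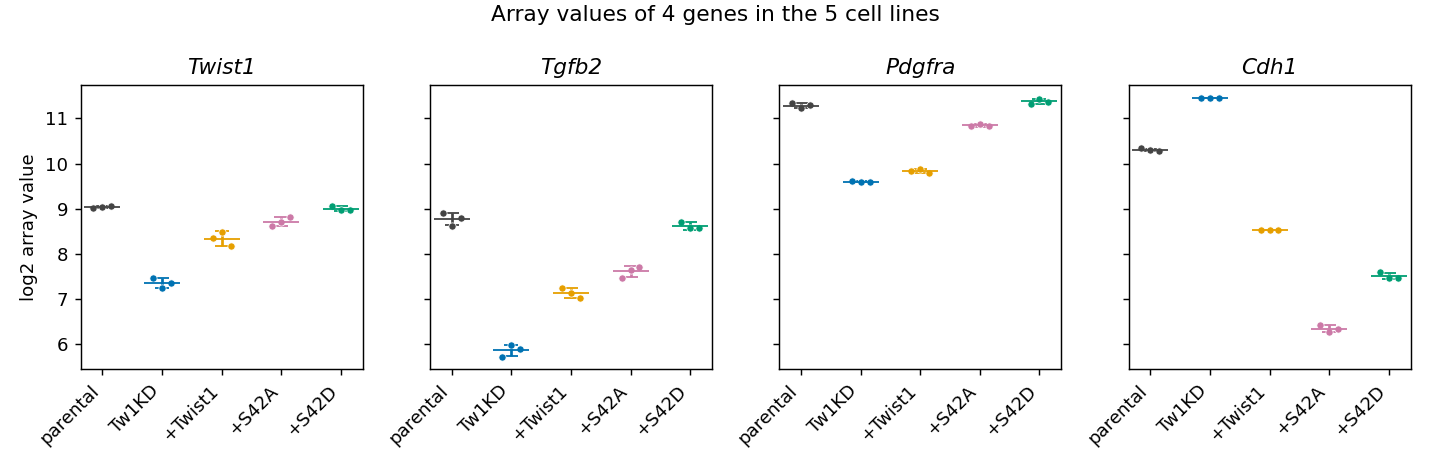
Log2 array value (vertical axis) of Twist1, Tgfb2, Pdgfra and Cdh1 in the 5 lines (horizontal axis), with a point per array, a long bar at the mean and error bars of 1 standard deviation. Tgfb2 lay at 8.77 ± 0.14 in parental cells and 5.85 ± 0.13 in Tw1KD cells, and Cdh1 was highest in Tw1KD cells (11.46 ± 0.0027) and lowest in the S42A line (6.34 ± 0.076).

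Tw1KD was compared with parental cells. Epithelial genes were called higher for 20 of 31 members (adjusted p = 0.088 with an estimated correlation for the list), among them the desmosomal Dsg2 (2.29 ± 0.10) and Dsp (2.21 ± 0.087) (log2 difference ± SE, n = 3) and Cdh1, the gene of E-cadherin (1.15 ± 0.045). Of TGF-beta pathway components, 16 of 34 were called lower and 9 higher (adjusted p = 0.20 with an estimated correlation), and the ligand genes Inhba (-4.13 ± 0.099) and Tgfb2 (-2.92 ± 0.090) fell. The growth factor receptors Pdgfra (-1.69 ± 0.043) and Pdgfrb (-2.09 ± 0.076) and the collagen gene Col6a1 (-2.18 ± 0.056) fell as well. Among the largest rises were those of Lilr4b (5.46 ± 0.14) and Aspa (4.40 ± 0.11) and of the cytokine Il24 (3.64 ± 0.099), and among the largest falls those of Hsd17b11 (-5.48 ± 0.098) and Ogn (-4.85 ± 0.11) and the receptor gene Calcrl (-4.15 ± 0.084). Lilr4b belongs to a family of near-identical genes, so the member read is uncertain.

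Among the epithelial junctions and keratins (31 measured), 20 rose, 3 fell (Esrp1, Krt8, Tjp1) and 8 were not called, with 23 called when adjusted within the list (camera adjusted p = 3.4e-07, adjusted p = 0.088 with an estimated correlation). The 3 that fell include the splicing regulator Esrp1 (-2.64 ± 0.086) and the tight junction gene Tjp1 (-0.28 ± 0.042). With 30 mesenchymal markers measured, 2 rose (Itga5, Mmp14), 9 fell and 19 were not called, with 11 called when adjusted within the list (camera adjusted p = 0.0054, adjusted p = 0.20 with an estimated correlation). The rise of Mmp14 was not called without parental replicate 1 or 2 or Tw1KD replicate 3 (0.11, 0.092 and 0.091), with median centring (0.14), with the neighbour correction (0.039) or with only these lines fitted. Of the 23 measured EMT transcription factors, 3 rose (Hmga2, Id1, Zeb1), 10 fell and 10 were not called, with 13 called when adjusted within the list (camera adjusted p = 0.020, adjusted p = 0.12 with an estimated correlation). Among these factors Id1 (1.24 ± 0.051) rose, and Sox4 (-0.93 ± 0.038) and Zeb2 (-0.85 ± 0.046) fell. Among the TGF-beta pathway components (34 measured), 9 rose, 16 fell and 9 were not called, with 25 called when adjusted within the list (camera adjusted p = 0.0060, adjusted p = 0.20 with an estimated correlation). With 20 cholesterol synthesis genes measured, 2 rose (Ebp, Tm7sf2), 16 fell and 2 were not called (Mvd, Sc5d), with 19 called when adjusted within the list (camera adjusted p = 3.7e-08, adjusted p = 0.15 with an estimated correlation). Examples are Idi1 (-1.22 ± 0.080) and Hsd17b7 (-1.14 ± 0.053). The rise of Tm7sf2 was not called without Tw1KD replicate 1 or 3 (0.23 and 0.23) or with the neighbour correction (0.14). Of the 31 measured genes of unfolded protein and amino acid stress, 19 rose, 3 fell (Hsp90b1, Manf, Slc7a11) and 9 were not called, with 22 called when adjusted within the list (camera adjusted p = 0.00021, adjusted p = 0.23 with an estimated correlation). The glutathione-degrading enzyme gene Chac1 (1.15 ± 0.050) and the stress gene Sesn2 (1.12 ± 0.094) were the largest of these rises, and the fall of Manf was not called with the neighbour correction (-0.085).

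Other lists were not called as groups but held large single changes. The matrix protein genes Ccn2 (-2.81 ± 0.047) and Ccn1 (-1.60 ± 0.037) fell in the TGF-beta response list (8 higher and 6 lower of 26, 18 adjusted within the list, camera adjusted p = 0.88), and the serpin gene Serpinb5 (2.55 ± 0.11) rose and Plat (-2.41 ± 0.091) and Mmp3 (-2.09 ± 0.072) fell among matrix proteases and inhibitors (9 higher and 13 lower of 35, 24 adjusted within the list, camera adjusted p = 0.23). The hypoxia marker Car9 (-1.76 ± 0.076) fell, while the glycolytic regulator Pfkfb4 (1.54 ± 0.059) rose. Further large rises were Slc26a9 (3.22 ± 0.049), Folr1 (3.08 ± 0.10), Dpep1 (3.06 ± 0.089), Anxa8 (3.06 ± 0.11), Dynap (3.04 ± 0.14), Dpep2 (3.87 ± 0.060) and Lncenc1 (4.19 ± 0.088). Further large falls were the Wnt antagonist Sfrp1 (-4.12 ± 0.081) and Igfbp7 (-3.98 ± 0.087), Gpm6b (-3.97 ± 0.063), Angpt1 (-3.95 ± 0.091), Cxcl15 (-3.89 ± 0.095) and Sorbs2 (-3.57 ± 0.11). Cdh2 (-0.086 ± 0.061), Vim (-0.024 ± 0.033) and Snai2 (0.00065) were not called, and Fn1 fell (-0.12 ± 0.037). Fn1 was not called without parental replicate 3 (-0.098) or Tw1KD replicate 1 (-0.10), nor with median centring (-0.084) or only these lines fitted. Cdh2, near the background, was called lower without Tw1KD replicate 2 (-0.17) and with array weights. Vim (13.46 to 13.55 log2) and Fn1 (12.85 to 13.36) lay near the array maxima (13.90 to 14.02) in every line, where differences can be compressed. In all, 7242 of 19937 genes were called (3970 higher, 3272 lower), 1589 of them at least 1.5-fold and 529 at least 2-fold. Median, mean and test differed in sign for TGF-beta response genes (median 0.069, mean -0.082, test up), PI3K-Akt pathway components (median 0.00019, mean 0.021, test down), hypoxia and glycolysis (median 0.071, mean -0.0062, test up), adhesion and integrins (median 0.0097, mean 0.0089, test down) and endothelial markers (median 0.038, mean 0.0077, test down), none of them called. In every comparison folds are understated where the lower line lay in the dimmest part of all group means, below 5.50 log2, as for Lilr4b, Aspa, Hsd17b11, Ogn and Sfrp1.

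Wild-type Twist1 was compared with Tw1KD. Epithelial genes fell for 23 of 31 members, with Epcam (-4.10 ± 0.21) and St14 (-4.04 ± 0.060) and Cdh1 (-2.94 ± 0.045) among them. Cell cycle genes rose for 38 of 40 members and cholesterol synthesis genes for 19 of 20, and interferon response genes fell for 27 of 34 (adjusted p = 0.11 with an estimated correlation). The chemokine gene Ccl2 (4.02 ± 0.16) and the stromelysin gene Mmp3 (3.0 ± 0.072) rose, as did Tgfb2 (1.27 ± 0.090). The largest rise was in Hsd17b11 (4.72 ± 0.098), followed by the tetraspanin gene Cd53 (4.36 ± 0.093) and Casp12 (4.20 ± 0.12). The largest fall was in the adhesion gene Mpzl2 (-5.37 ± 0.11).

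Among the epithelial junctions and keratins (31 measured), 1 rose (Krt8), 23 fell and 7 were not called, with 25 called when adjusted within the list (camera adjusted p = 4.7e-11, held with an estimated correlation at adjusted p = 0.022). With 40 cell cycle genes measured, 38 rose, 1 fell (Ccnd2) and 1 was not called (E2f2), with 39 called when adjusted within the list (camera adjusted p = 4.4e-21, held with an estimated correlation at adjusted p = 0.046). The mitotic kinesin gene Kif20a (1.77 ± 0.047) and the cyclin gene Ccne2 (1.65 ± 0.078) were the largest rises, and the cyclin gene Ccnd2 (-0.75 ± 0.035) fell. Of the 20 measured cholesterol synthesis genes, 19 rose and 1 fell (Tm7sf2), with 20 called when adjusted within the list (camera adjusted p = 2.7e-13, held with an estimated correlation at adjusted p = 0.046). Examples are Hsd17b7 (2.77 ± 0.053) and Idi1 (2.36 ± 0.080). Among the interferon response genes (34 measured), 2 rose (Ifit2, Ifit3), 27 fell and 5 were not called (B2m, Gbp3, Ifit1, Mx1, Oasl1), with 29 called when adjusted within the list (camera adjusted p = 1.2e-07, adjusted p = 0.11 with an estimated correlation). The nuclease gene Isg20 (-1.84 ± 0.049) and the signalling factor Irf9 (-1.67 ± 0.040) fell, against a rise of Ifit2 (2.19 ± 0.084). With 32 hypoxia and glycolysis genes measured, 7 rose, 15 fell and 10 were not called, with 23 called when adjusted within the list (camera adjusted p = 0.045, adjusted p = 0.17 with an estimated correlation). The carbonic anhydrase gene Car12 (-2.48 ± 0.049) fell. Of the 31 measured genes of unfolded protein and amino acid stress, 9 rose, 19 fell and 3 were not called (Atf4, Phgdh, Psat1), with 28 called when adjusted within the list (camera adjusted p = 0.045, adjusted p = 0.54 with an estimated correlation). Trib3 (-1.13 ± 0.050) was the largest of these falls. Among the adhesion and integrin genes (35 measured), 9 rose, 17 fell and 9 were not called, with 26 called when adjusted within the list (camera adjusted p = 0.045, adjusted p = 0.38 with an estimated correlation). The laminin chain Lamb3 (-2.45 ± 0.060) fell and the adhesion molecule Vcam1 (1.55 ± 0.060) rose. These last 3 calls were lost without Tw1KD replicate 3 (adjusted p = 0.081 for each). The stress call was also lost without Tw1KD replicate 1 (0.051), and the stress and adhesion calls without wild-type replicate 3 (0.057 and 0.055). With the replicate number as a block all 3 were lost (0.055, 0.055 and 0.055). The neighbour correction ended the hypoxia (0.10) and stress calls (0.069), and leaving out the dimmest genes ended the adhesion call (0.089).

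Mesenchymal markers and EMT transcription factors were not called as groups on return of wild-type Twist1 (11 higher and 4 lower (Fap, Fn1, Itgb3, Mmp14) of 30, 18 adjusted within the list, camera adjusted p = 0.30; 9 higher and 3 lower (Foxc1, Klf8, Tcf4) of 23, 12 adjusted within the list, camera adjusted p = 0.10). Single members rose, such as Col6a1 (2.05 ± 0.056), Pdgfrb (1.57 ± 0.076) and Zeb2 (1.06 ± 0.046). The insulin receptor substrate gene Irs1 (2.77 ± 0.061) rose and the receptor gene Erbb3 (-2.31 ± 0.086) fell within the PI3K-Akt list (8 higher and 17 lower of 38, 26 adjusted within the list, camera adjusted p = 0.28; called lower with quantile normalization, adjusted p = 0.043). Matrix proteases and inhibitors (7 higher and 17 lower of 35, 26 adjusted within the list, camera adjusted p = 0.073) were called lower with median centring only (adjusted p = 0.0498). The p53 effector gene Perp (-3.74 ± 0.091) fell. Pdgfra rose by only 0.24 ± 0.043. Vim (0.093 ± 0.033) and Fn1 (-0.11 ± 0.037) passed the threshold with small differences. Vim turned to -0.39 with the neighbour correction and was not called without Tw1KD replicate 1 or 2 (0.095 and 0.087) or wild-type replicate 1 or 3 (0.085 and 0.083), nor with the replicate block or only these lines fitted. Fn1 was not called without Tw1KD replicate 3 (-0.091) or wild-type replicate 2 or 3 (-0.089 and -0.11), nor with median centring (-0.017), quantile normalization (-0.065) or only these lines fitted. Foxc1 among the EMT factors was not called with median centring (-0.12), without Tw1KD replicate 3 (-0.15) or without wild-type replicate 1 (-0.19). Cdh2 (-0.027) and Snai2 (-0.11) were not called. Further large rises were Gpm6b (4.10 ± 0.063), Dpt (3.98 ± 0.12), Sorbs2 (3.56 ± 0.11), Nlrp4e (3.59 ± 0.14), Mmp1b (3.54 ± 0.14) and Rnase2a (3.45 ± 0.15), the last 3 from families of near-identical genes. Further large falls were Lilr4b (-5.21 ± 0.14), Xlr (-4.86 ± 0.20), Aspa (-4.84 ± 0.11), Il24 (-4.37 ± 0.099), Dpep2 (-4.37 ± 0.060), Tmc4 (-3.91 ± 0.071) and Lncenc1 (-3.91 ± 0.088), with Xlr and Lilr4b likewise uncertain. In all, 9566 of 19937 genes were called (4686 higher, 4880 lower), 2808 of them at least 1.5-fold and 965 at least 2-fold. The share of calls that were higher depends on the scaling: 49.0% of the called genes were higher, against 64.3% with each array centred on its own median. The signs of median, mean and test differed for mesenchymal markers (median -0.069, mean 0.15, test up), reported Twist1 targets (median -0.039, mean 0.095, test up), TGF-beta pathway components (median -0.056, mean -0.014, test up), cytokines and chemokines (median -0.11, mean 0.11, test down) and fibroblast markers (median -0.085, mean 0.22, test up), none of them called.

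S42A was compared with Tw1KD. Epithelial genes fell for 23 of 31 members, with Cldn4 (-5.31 ± 0.12), Cdh1 (-5.12 ± 0.045) and Krt19 (-5.09 ± 0.081). Interferon response genes rose for 25 of 34 (adjusted p = 0.069 with an estimated correlation), with Ifit2 (3.42 ± 0.084) and Ifit1 (2.73 ± 0.10). Pdgfra (1.25 ± 0.043) and Tgfb2 (1.75 ± 0.090) rose. The largest rises were in the transglutaminase gene F13a1 (5.07 ± 0.074), the angiopoietin gene Angpt1 (4.37 ± 0.091) and Trim30a (4.18 ± 0.089), a member of a near-identical family. They were followed by Dpt (4.13 ± 0.12), the metabolic coactivator Ppargc1a (4.05 ± 0.11) and Casp1 (3.99 ± 0.097). Besides Cldn4, Cdh1 and Krt19 the largest falls were in Mpzl2 (-5.48 ± 0.11), Lilr4b (-5.37 ± 0.14) and Perp (-5.25 ± 0.091).

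With 31 epithelial junctions and keratins measured, 1 rose (Krt8), 23 fell and 7 were not called, with 24 called when adjusted within the list (camera adjusted p = 1.4e-13, held with an estimated correlation at adjusted p = 0.0094). Of the 34 measured interferon response genes, 25 rose, 3 fell (Irf9, Isg20, Tap1) and 6 were not called, with 29 called when adjusted within the list (camera adjusted p = 3.3e-09, adjusted p = 0.069 with an estimated correlation). Among the cell cycle genes (40 measured), 35 rose, 1 fell (Ccnd2) and 4 were not called (Cdk2, E2f2, Kif11, Mcm3), with 36 called when adjusted within the list (camera adjusted p = 3.4e-17, adjusted p = 0.069 with an estimated correlation). Kif20a (1.77 ± 0.047) and the thymidylate synthase gene Tyms (1.59 ± 0.048) led these rises. With 20 cholesterol synthesis genes measured, 18 rose and 2 fell (Ebp, Tm7sf2), with 20 called when adjusted within the list (camera adjusted p = 2.1e-11, adjusted p = 0.069 with an estimated correlation). Of the 31 measured genes of unfolded protein and amino acid stress, 5 rose (Creld2, Hsp90b1, Manf, Pdia3, Pdia6), 21 fell and 5 were not called (Calr, Canx, Hspa5, Pdia4, Sdf2l1), with 27 called when adjusted within the list (camera adjusted p = 1.0e-06, adjusted p = 0.12 with an estimated correlation). Chac1 (-1.80 ± 0.050) and Trib3 (-1.51 ± 0.050) fell the most. With the neighbour correction Pdia6 (0.078) and Irf9 (-0.12) were not called. The gelatinase gene Mmp9 (-3.75 ± 0.057) and the chemokine gene Cxcl16 (-4.49 ± 0.11) fell, and Mmp3 (3.09 ± 0.072) and the lymphatic growth factor gene Vegfc (2.54 ± 0.086) rose.

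Fn1 fell in the S42A line (-0.39 ± 0.037), and Vim (0.033), Cdh2 (0.094) and Snai2 (-0.048) were not called. Cdh2, near the background, was called higher without Tw1KD replicate 2 (0.18) and with array weights (0.17); with quantile normalization Cdh2 (0.17) and Vim (0.095) were called higher. In all, 8470 of 19937 genes were called (4538 higher, 3932 lower), 2481 of them at least 1.5-fold and 965 at least 2-fold. Mesenchymal markers (12 higher and 4 lower (Cdh11, Fn1, Itgb3, Mmp14) of 30, 16 adjusted within the list, camera adjusted p = 0.059) were not called, but adjusted p was 0.022 without Tw1KD replicate 2, 0.048 without S42A replicate 2 and 0.043 without S42A replicate 3, and 0.043, 0.046 and 0.021 with quantile normalization, median centring and the neighbour correction. For the p53 response (8 higher and 13 lower of 26, 21 adjusted within the list, camera adjusted p = 0.071) it was 0.031 without Tw1KD replicate 2 and 0.044 without S42A replicate 3, and 0.031, 0.032 and 0.021 in those 3 settings. Adhesion and integrin genes (10 higher and 15 lower of 35, 25 adjusted within the list, camera adjusted p = 0.091) were called lower in the same settings (0.043, 0.032 and 0.015). Median, mean and test differed in sign for reported Twist1 targets (median 0.036, mean -0.074, test up), TGF-beta pathway components (median -0.023, mean 0.043, test down), PI3K-Akt pathway components (median 0.0035, mean -0.098, test down), hypoxia and glycolysis (median 0.040, mean -0.24, test down), stem and mammary lineage markers (median -0.029, mean -0.024, test up) and macrophage and leukocyte markers (median -0.0073, mean 0.0068, test down), none of them called.

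S42D was compared with Tw1KD. Epithelial genes fell for 20 of 31 members, with Cldn4 (-5.46 ± 0.12), St14 (-4.78 ± 0.060) and Dsp (-4.24 ± 0.087). Of mesenchymal markers, 10 of 30 were called higher (adjusted p = 0.17 with an estimated correlation), Col6a1 (4.21 ± 0.056) and Pdgfrb (4.19 ± 0.076) the most. Of TGF-beta pathway components, 18 of 34 were called higher (adjusted p = 0.13 with an estimated correlation), with Inhba (4.10 ± 0.099) and Tgfb2 (2.76 ± 0.090). The vascular cadherin gene Cdh5 (4.68 ± 0.087) and the interleukin gene Il33 (2.53 ± 0.14) rose. The largest rises were in F13a1 (6.50 ± 0.074), Cd53 (5.97 ± 0.093), Cd28 (5.84 ± 0.079), Hsd17b11 (5.72 ± 0.098) and Angptl7 (5.40 ± 0.086) and the proteoglycan gene Bgn (4.75 ± 0.094). The largest falls after Cldn4 and St14 were in Zdhhc23 (-4.51 ± 0.13), Mpzl2 (-4.46 ± 0.11) and Il24 (-4.29 ± 0.099).

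Among the epithelial junctions and keratins (31 measured), 2 rose (Krt8, Tjp1), 20 fell and 9 were not called, with 23 called when adjusted within the list (camera adjusted p = 2.7e-09, held with an estimated correlation at adjusted p = 0.038). With 30 mesenchymal markers measured, 10 rose, 2 fell (Cdh11, Itgb3) and 18 were not called, with 12 called when adjusted within the list (camera adjusted p = 0.0060, adjusted p = 0.17 with an estimated correlation). Of the 23 measured EMT transcription factors, 10 rose, 3 fell (Foxc2, Id1, Id3) and 10 were not called, with 13 called when adjusted within the list (camera adjusted p = 0.023, adjusted p = 0.13 with an estimated correlation). Id2 (1.18 ± 0.053) and Zeb2 (0.98 ± 0.046) rose and Id3 (-1.28 ± 0.082) and Id1 (-0.86 ± 0.051) fell. Among the TGF-beta pathway components (34 measured), 18 rose, 5 fell (Acvr1b, Itgb6, Ltbp4, Tgfbr1, Zfyve9) and 11 were not called, with 23 called when adjusted within the list (camera adjusted p = 0.00070, adjusted p = 0.13 with an estimated correlation). With 35 matrix proteases and inhibitors measured, 15 rose, 8 fell and 12 were not called, with 23 called when adjusted within the list (camera adjusted p = 0.037, adjusted p = 0.17 with an estimated correlation). Plat, the tissue plasminogen activator gene (3.37 ± 0.091), and Mmp3 (3.11 ± 0.072) rose the most. Of the 35 measured adhesion and integrin genes, 18 rose, 7 fell and 10 were not called, with 26 called when adjusted within the list (camera adjusted p = 0.014, adjusted p = 0.23 with an estimated correlation). The integrin gene Itga1 (2.59 ± 0.072) rose and Itga2 (-3.09 ± 0.090) fell. Among the cell cycle genes (40 measured), 32 rose, 2 fell (Ccnd2, Mcm5) and 6 were not called, with 35 called when adjusted within the list (camera adjusted p = 3.3e-12, adjusted p = 0.13 with an estimated correlation). Mcm5, the weaker fall (-0.14 ± 0.033), turned to 0.10 with the neighbour correction, which also ended the calls of Tjp1 (0.12) and Itgb3 (-0.15). Tjp1 was not called with quantile normalization (0.11) nor Mcm5 with median centring (-0.090) or only these lines fitted. With 20 cholesterol synthesis genes measured, 15 rose, 1 fell (Tm7sf2) and 4 were not called (Ebp, Msmo1, Mvd, Sqle), with 17 called when adjusted within the list (camera adjusted p = 6.5e-06, adjusted p = 0.17 with an estimated correlation). Of the 31 measured genes of unfolded protein and amino acid stress, 8 rose, 18 fell and 5 were not called (Calr, Canx, Ddit3, Dnajc3, Slc7a11), with 27 called when adjusted within the list (camera adjusted p = 0.037, adjusted p = 0.49 with an estimated correlation). Atf3 (-1.65 ± 0.066) fell the most.

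Cdh1 (-3.95 ± 0.045) fell and Pdgfra (1.78 ± 0.043) rose in the S42D line. Vim (0.049), Fn1 (-0.040), Cdh2 (0.0052) and Snai2 (-0.097) were not called; Fn1 turned to 0.13 with the neighbour correction, and Vim was called higher with quantile normalization (0.095) and with trend and robust settings. In all, 8646 of 19937 genes were called (4321 higher, 4325 lower), 2385 of them at least 1.5-fold and 908 at least 2-fold. The EMT factor call was lost when the dimmest genes were left out (adjusted p = 0.063), the protease call with quantile normalization (0.054) and without Tw1KD replicate 3 (0.055), and the stress call without Tw1KD replicate 3 (0.082) and with the neighbour correction (0.072). The p53 response (5 higher (Ei24, Fas, Gtse1, Pidd1, Zmat3) and 14 lower of 26, 21 adjusted within the list, camera adjusted p = 0.056) was called without Tw1KD replicate 2 (0.024) or S42D replicate 1 (0.026), with quantile normalization (0.025), median centring (0.042) or the neighbour correction (0.0087), and without the dimmest genes (0.048). Median, mean and test differed in sign for reported Twist1 targets (median -0.0050, mean 0.018, test up), TGF-beta response genes (median -0.056, mean 0.072, test up), PI3K-Akt pathway components (median 0.016, mean -0.038, test up), cytokines and chemokines (median -0.026, mean 0.26, test up), stem and mammary lineage markers (median -0.028, mean -0.017, test up) and endothelial markers (median -0.10, mean 0.25, test down), none of them called.

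**Figure D2:**
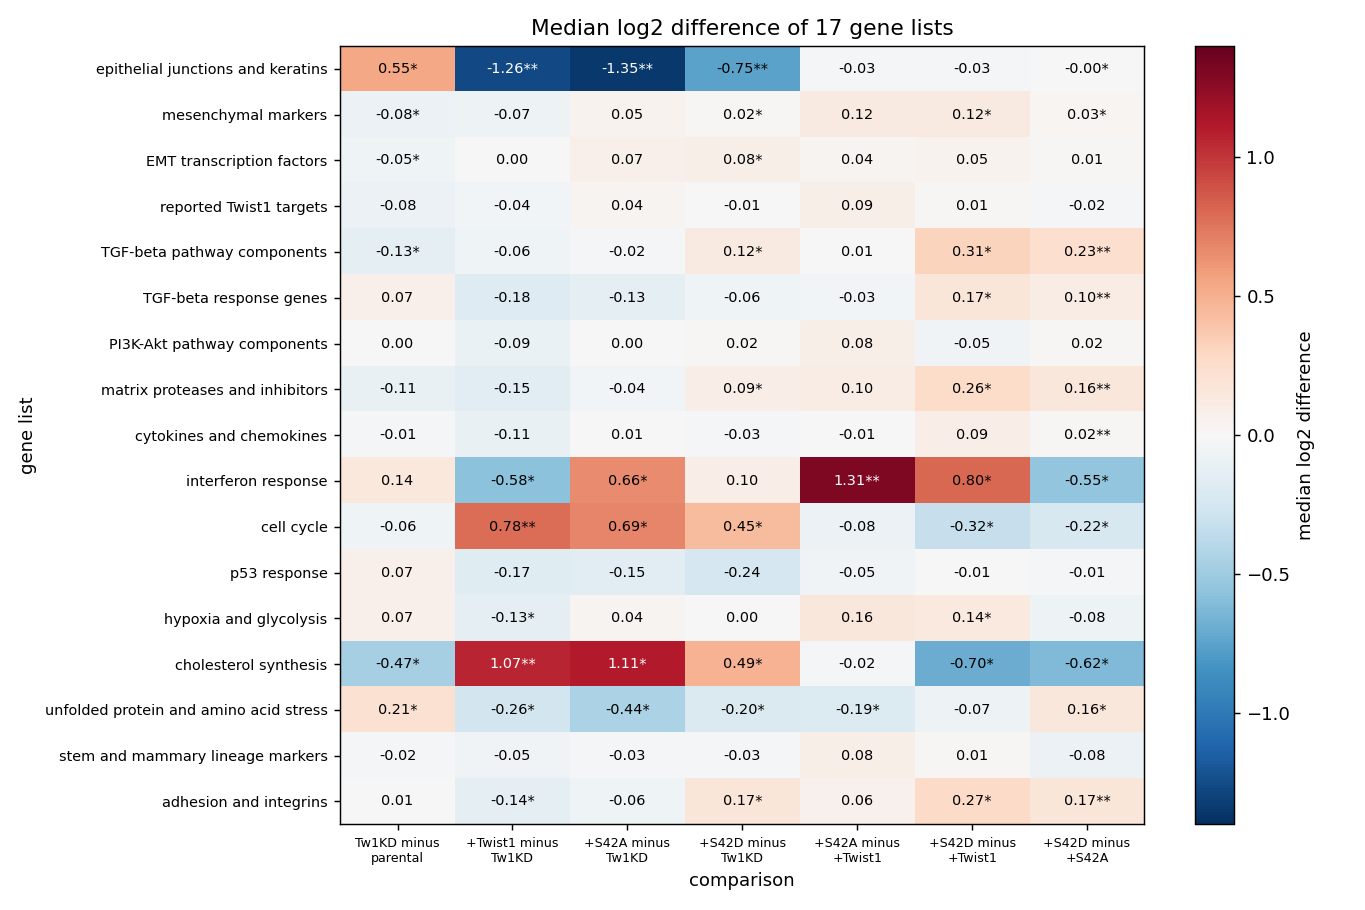
Median log2 difference (colour and printed number) of the 17 primary gene lists (vertical axis) in the 7 main comparisons (horizontal axis), where 1 asterisk marks camera adjusted p under 0.05 and a pair of asterisks a call that held with an estimated correlation. Epithelial genes had medians of -1.26, -1.35 and -0.75 in the wild-type, S42A and S42D lines against Tw1KD, while the interferon medians were -0.58, 0.66 and 0.097.

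Of the 7242 genes called in Tw1KD against parental cells, 3964 (54.7%) were reversed in the wild-type line and 1516 were called further away. The counts were 4354 (60.1%) and 1061 for S42A, and 4945 (68.3%) and 688 for S42D. Hsd17b11, which had fallen by 5.48 log2, rose by 4.72 with wild-type Twist1 and 5.72 with S42D. In the S42A line it remained 47.8-fold lower than in parental cells. Tgfb2 lay -1.65 from parental cells in the wild-type line and -1.16 in the S42A line, both called, and -0.16 in the S42D line, not called (array weights called it). Pdgfra lay at -1.45, -0.44 and 0.092, the last not called except with median centring. Cdh1 went below the parental level in all 3 lines, at -1.79, -3.97 and -2.81 log2.

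Against parental cells, 1475 of the genes reversed in the wild-type line were not called, 1716 were called beyond the parental level and 773 short of it. The counts were 1858, 1713 and 783 for S42A, and 2369, 1809 and 767 for S42D. All 3 lines reversed 2762 genes and none reversed 1252. Only S42D reversed 852, only the wild-type line 359 and only S42A 268; whether the lines differ at each of these genes was not tested. Of the 529 genes changed at least 2-fold on depletion, 328 were reversed in all 3 lines and 24 in none. Independent lists of the same sizes would share 1741, 1528 and 1570 genes. An unchanged line, with few calls to share, gave 0.100, 0.0667 and 0.0333 genes on average. Across genes the covariance of both sets of differences was -0.0887, -0.104 and -0.127, against simulated values of -0.00302, -0.00297 and -0.00300. Part of each count can still come from the shared Tw1KD arrays.

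**Figure D3:**
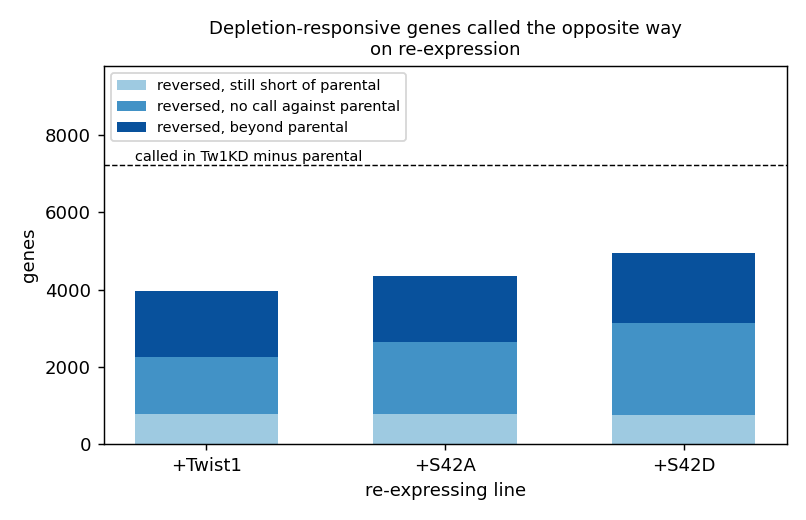
Number of genes called on depletion (vertical axis) and called the opposite way in each re-expressing line (horizontal axis). Bars are stacked by the call against parental cells, and a dashed line marks all 7242 genes. The bars reach 3964, 4354 and 4945 genes.

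S42A was compared with wild-type Twist1. Interferon response genes were higher in the S42A line for 33 of 34 members, with Usp18 (3.63 ± 0.069) and Irf7 (3.46 ± 0.13) the largest of them and the antiviral gene Samd9l (4.05 ± 0.085) among the largest rises of the comparison. Cdh1 was lower (-2.18 ± 0.045), as were the keratin gene Krt19 (-2.73 ± 0.081) and Cldn4 (-2.46 ± 0.12). Pdgfra (1.01 ± 0.043) and Tgfb2 (0.49 ± 0.090) were higher, as Twist1 itself was. The mitochondrial coactivator gene Ppargc1a (5.76 ± 0.11), the integrin gene Itga8 (4.91 ± 0.069) and the scaffold gene Cask (4.67 ± 0.10) rose. The creatine synthesis gene Gatm (-4.94 ± 0.11), the lysosomal Hexa (-4.33 ± 0.13) and Hsd17b11 (-4.82 ± 0.098), Bckdhb (-4.34 ± 0.11), Parvb (-4.07 ± 0.051) and Cd53 (-4.02 ± 0.093) fell.

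Among the interferon response genes (34 measured), 33 rose, 0 fell and 1 was not called (B2m), with 33 called when adjusted within the list (camera adjusted p = 1.7e-24, held with an estimated correlation at adjusted p = 0.010). With 31 genes of unfolded protein and amino acid stress measured, 4 rose (Asns, Canx, Hspa5, Pdia4), 20 fell and 7 were not called, with 25 called when adjusted within the list (camera adjusted p = 1.9e-05, adjusted p = 0.28 with an estimated correlation). Chac1 (-1.35 ± 0.050) and Sesn2 (-0.93 ± 0.094) fell the most, and the rises of Pdia4 (0.13) and Hspa5 (0.12) were not called with median centring, nor Pdia4 with the neighbour correction (0.067). The interleukin gene Il33 (2.55 ± 0.14) and the chemokine gene Cxcl10 (1.63 ± 0.11) rose, and Cxcl16 (-2.52 ± 0.11) and Ccl7 (-2.44 ± 0.11) fell, in a list that was not called (9 higher and 14 lower of 41, 24 adjusted within the list, camera adjusted p = 0.47). Epithelial genes as a list (5 higher (Krt7, Ocln, Pkp2, Pkp3, Tjp1) and 12 lower of 31, 18 adjusted within the list, camera adjusted p = 0.055) and hypoxia and glycolysis genes (17 higher and 6 lower of 32, 24 adjusted within the list, camera adjusted p = 0.055) were not called either. Without S42A replicate 1 both were (adjusted p = 0.032 and 0.032), and without wild-type replicate 1 the hypoxia list was (0.046). Quantile normalization also called both (0.049 and 0.019), and median centring the epithelial list (0.041). Xlr (6.2 ± 0.20) and Trim30a (4.62 ± 0.089) were the other large rises, each from a near-identical family. Vim (-0.060) was not called, was called lower with array weights and with trend and robust settings and was called higher (0.43) with the neighbour correction; Fn1 fell (-0.28 ± 0.037), a value of -0.090 that was not called with that correction. Snai2 (0.057) and Cdh2 (0.12) were not called, Cdh2 being called higher with array weights or with only these lines fitted. In all, 7978 of 19937 genes were called (3986 higher, 3992 lower), 1768 of them at least 1.5-fold and 631 at least 2-fold. The signs of median, mean and test differed for EMT transcription factors (median 0.039, mean -0.020, test down), reported Twist1 targets (median 0.087, mean -0.17, test down) and TGF-beta pathway components (median 0.0062, mean 0.058, test down), none of them called.

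**Figure D4:**
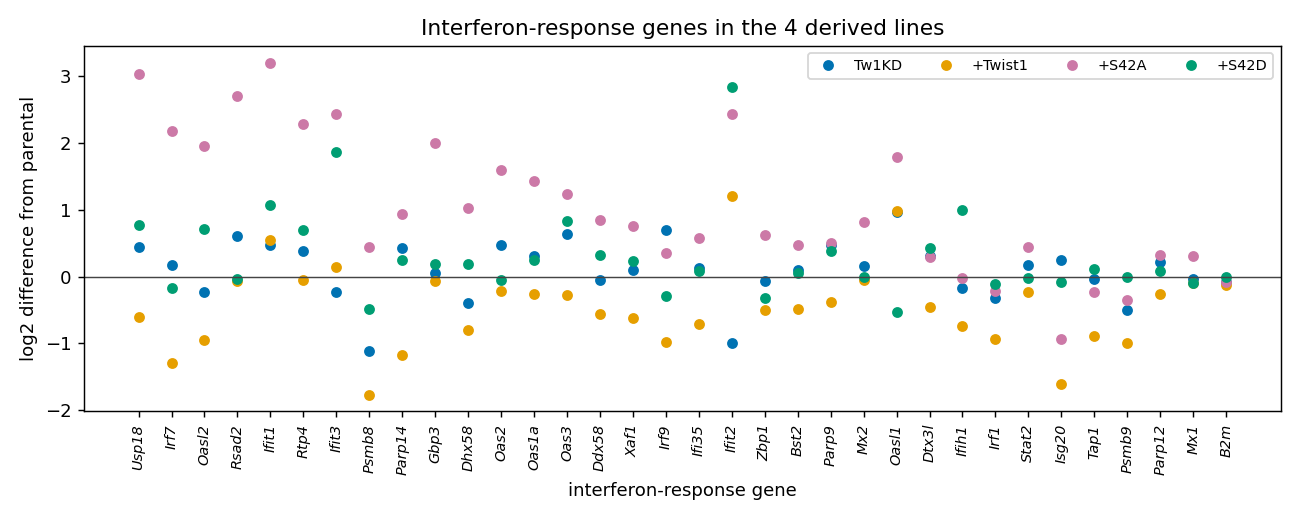
Log2 difference from parental cells (vertical axis) of the 34 measured interferon response genes (horizontal axis), with a point for the mean of 3 arrays of each derived line. In the S42A line 28 genes were called higher and 4 lower (Irf1, Isg20, Psmb9, Tap1) than in parental cells, against 3 higher (Ifit1, Ifit2, Oasl1) and 23 lower in the wild-type line.

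S42D was compared with wild-type Twist1. Called higher in the S42D line were 20 of 34 TGF-beta pathway components, 20 of 35 matrix proteases and inhibitors, 21 of 35 adhesion genes and 11 of 30 mesenchymal markers (adjusted p = 0.060, 0.052, 0.076 and 0.10 with an estimated correlation). Called lower were 30 of 40 cell cycle and 16 of 20 cholesterol synthesis genes (adjusted p = 0.12 and 0.10 with an estimated correlation). Examples of the rises are Inhba (2.32 ± 0.099), Tgfb2 (1.49 ± 0.090), Mmp9 (2.03 ± 0.057) and Cdh5 (4.31 ± 0.087) and the collagen gene Col6a2 (2.82 ± 0.062). Among the largest rises were the growth factor gene Pdgfc (5.46 ± 0.073), the receptor tyrosine kinase antagonist Spry1 (5.08 ± 0.057), the interleukin gene Il33 (4.72 ± 0.14) and Angptl7 (5.38 ± 0.086). The largest falls were in Gatm (-4.86 ± 0.11), Tmem185b (-4.40 ± 0.054), Trim44 (-3.75 ± 0.063), Dbt (-3.32 ± 0.051), Aldh1l2 (-3.04 ± 0.11) and Rassf6 (-3.03 ± 0.13). Cdh1 was lower (-1.02 ± 0.045) and Pdgfra higher (1.54 ± 0.043).

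Of the 34 measured TGF-beta pathway components, 20 rose, 5 fell (Acvr1, Acvr1b, Smad7, Tgfbr1, Zfyve9) and 9 were not called, with 25 called when adjusted within the list (camera adjusted p = 1.5e-05, adjusted p = 0.060 with an estimated correlation). Among the TGF-beta response genes (26 measured), 12 rose, 3 fell (Il11, Smad7, Tgfbi) and 11 were not called, with 17 called when adjusted within the list (camera adjusted p = 0.014, adjusted p = 0.10 with an estimated correlation). With 35 matrix proteases and inhibitors measured, 20 rose, 3 fell (Ctsk, Mmp12, Mmp1a) and 12 were not called, with 25 called when adjusted within the list (camera adjusted p = 2.4e-05, adjusted p = 0.052 with an estimated correlation). The fall of Ctsk was not called without wild-type replicate 1 or 2 or S42D replicate 1 (-0.26, -0.25 and -0.29). Of the 35 measured adhesion and integrin genes, 21 rose, 4 fell (Icam1, Itga2, Lamb3, Vcam1) and 10 were not called, with 25 called when adjusted within the list (camera adjusted p = 1.5e-05, adjusted p = 0.076 with an estimated correlation). Among the mesenchymal markers (30 measured), 11 rose, 3 fell (Cdh11, Lox, Tnc) and 16 were not called, with 14 called when adjusted within the list (camera adjusted p = 0.0040, adjusted p = 0.10 with an estimated correlation).

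With 34 interferon response genes measured, 28 rose, 1 fell (Oasl1) and 5 were not called (Gbp3, Mx1, Mx2, Oas2, Rsad2), with 29 called when adjusted within the list (camera adjusted p = 3.8e-11, adjusted p = 0.060 with an estimated correlation). Of the 32 measured hypoxia and glycolysis genes, 15 rose, 8 fell and 9 were not called, with 24 called when adjusted within the list (camera adjusted p = 0.028, adjusted p = 0.10 with an estimated correlation). Car12 (4.54 ± 0.049) and Aldoc (2.19 ± 0.079) rose, and the list's call was lost when the dimmest genes were left out (adjusted p = 0.059). Among the cell cycle genes (40 measured), 2 rose (Ccna2, Ccnd1), 30 fell and 8 were not called, with 32 called when adjusted within the list (camera adjusted p = 2.6e-08, adjusted p = 0.12 with an estimated correlation). Ccne2 (-1.51 ± 0.078) and the helicase gene Mcm3 (-1.03 ± 0.041) fell the most. With 20 cholesterol synthesis genes measured, 2 rose (Dhcr7, Insig1), 16 fell and 2 were not called (Pmvk, Tm7sf2), with 18 called when adjusted within the list (camera adjusted p = 1.7e-07, adjusted p = 0.10 with an estimated correlation). Of 31 epithelial genes, 6 rose and 9 fell, with Ocln (2.30 ± 0.078) and Krt7 (1.63 ± 0.056) against Cldn4 (-2.61 ± 0.12) and Dsp (-1.86 ± 0.087), and the list was not called (16 adjusted within the list, camera adjusted p = 0.62). The rises of Ccnd1 (0.13 ± 0.034) and Ccna2 (0.12 ± 0.035) turned to -0.018 and -0.23 with the neighbour correction and were not called with median centring (0.090 and 0.080). Vim (-0.045), Fn1 (0.068), Cdh2 (0.032) and Snai2 (0.0080) were not called; with the neighbour correction Vim (0.41) and Fn1 (0.36) were called higher. With trend and robust settings Vim was called lower and Fn1 higher, and Fn1 also with array weights (0.083). In all, 8630 of 19937 genes were called (4133 higher, 4497 lower), 2666 of them at least 1.5-fold and 961 at least 2-fold. Xlr (5.57 ± 0.20) and Trim30a (5.08 ± 0.089) rose, each from a near-identical family. Median, mean and test differed in sign for EMT transcription factors (median 0.046, mean -0.042, test up), reported Twist1 targets (median 0.013, mean -0.077, test up) and PI3K-Akt pathway components (median -0.054, mean 0.11, test up), none of them called.

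S42D was compared with S42A. The lists of TGF-beta components and responses, matrix proteases, cytokines and adhesion genes were called higher in the S42D line and held with an estimated correlation, with Inhba (2.67 ± 0.099), the co-receptor gene Tgfbr3 (1.52 ± 0.049), Mmp9 (3.52 ± 0.057) and Cxcl16 (2.61 ± 0.11) and the integrin gene Itga7 (2.61 ± 0.070). Called lower were 25 of 34 interferon response, 27 of 40 cell cycle and 17 of 20 cholesterol synthesis genes (adjusted p = 0.077, 0.19 and 0.082 with an estimated correlation), with Rsad2 (-2.73 ± 0.057), Irf7 (-2.35 ± 0.13), Ccne1 (-1.20 ± 0.053) and Cyp51 (-1.76 ± 0.096). Cdh1 (1.17 ± 0.045), Krt19 (2.62 ± 0.081) and Tgfb2 (1.01 ± 0.090) were higher. The largest rises were in Hsd17b11 (5.81 ± 0.098) and Cd53 (5.63 ± 0.093), the semaphorin gene Sema7a (5.39 ± 0.086) and Angptl7 (5.36 ± 0.086), Gstm5 (4.90 ± 0.081) and St3gal6 (4.75 ± 0.067). The largest falls were in Cask (-4.49 ± 0.10), Lurap1l (-4.05 ± 0.077), Trp53i11 (-3.91 ± 0.098), Adal (-3.44 ± 0.15), Mboat2 (-3.42 ± 0.10) and Otop1 (-3.31 ± 0.066).

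Of the 34 measured TGF-beta pathway components, 21 rose, 3 fell (Ltbp4, Tgfbr1, Zfyve9) and 10 were not called, with 24 called when adjusted within the list (camera adjusted p = 1.2e-07, held with an estimated correlation at adjusted p = 0.032). The fall of Zfyve9 was not called with the neighbour correction (-0.17). Among the TGF-beta response genes (26 measured), 12 rose, 1 fell (Nuak1) and 13 were not called, with 13 called when adjusted within the list (camera adjusted p = 6.4e-05, held with an estimated correlation at adjusted p = 0.032). With 35 matrix proteases and inhibitors measured, 16 rose, 4 fell (Adamts1, Mmp10, Mmp12, Mmp1a) and 15 were not called, with 21 called when adjusted within the list (camera adjusted p = 0.00012, held with an estimated correlation at adjusted p = 0.032). Of the 41 measured cytokines and chemokines, 17 rose, 7 fell and 17 were not called, with 25 called when adjusted within the list (camera adjusted p = 0.014, held with an estimated correlation at adjusted p = 0.045). Among the adhesion and integrin genes (35 measured), 19 rose, 4 fell (Itga2, Lamb3, Mcam, Vcam1) and 12 were not called, with 23 called when adjusted within the list (camera adjusted p = 3.8e-06, held with an estimated correlation at adjusted p = 0.045). With 30 mesenchymal markers measured, 11 rose, 2 fell (Acta2, Postn) and 17 were not called, with 13 called when adjusted within the list (camera adjusted p = 0.0083, adjusted p = 0.15 with an estimated correlation). Of the 31 measured genes of unfolded protein and amino acid stress, 17 rose, 2 fell (Asns, Atf3) and 12 were not called, with 21 called when adjusted within the list (camera adjusted p = 2.1e-05, adjusted p = 0.13 with an estimated correlation). The DNA damage and hypoxia gene Ddit4 (0.81 ± 0.047) rose the most there. Asns, the asparagine synthetase gene, fell (-0.15 ± 0.037) but turned to 0.18 with the neighbour correction.

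Among the epithelial junctions and keratins (31 measured), 10 rose, 2 fell (Elf3, St14) and 19 were not called, with 12 called when adjusted within the list (camera adjusted p = 0.013, adjusted p = 0.19 with an estimated correlation). Their median was -0.0016 and their mean 0.28. With 34 interferon response genes measured, 5 rose (Ifih1, Ifit2, Isg20, Psmb9, Tap1), 25 fell and 4 were not called (B2m, Dtx3l, Irf1, Parp9), with 32 called when adjusted within the list (camera adjusted p = 2.1e-07, adjusted p = 0.077 with an estimated correlation). Of the 40 measured cell cycle genes, 1 rose (Mcm4), 27 fell and 12 were not called, with 28 called when adjusted within the list (camera adjusted p = 3.8e-06, adjusted p = 0.19 with an estimated correlation). The rise of Mcm4 (0.18 ± 0.037) turned to -0.012 with the neighbour correction. Among the cholesterol synthesis genes (20 measured), 2 rose (Ebp, Tm7sf2), 17 fell and 1 was not called (Insig1), with 19 called when adjusted within the list (camera adjusted p = 1.2e-07, adjusted p = 0.082 with an estimated correlation). Pdgfra (0.53 ± 0.043) and Fn1 (0.35 ± 0.037) were higher, and Vim (0.015), Cdh2 (-0.089) and Snai2 (-0.049) were not called. In all, 7205 of 19937 genes were called (3400 higher, 3805 lower), 1584 of them at least 1.5-fold and 630 at least 2-fold. Median, mean and test differed in sign for EMT transcription factors (median 0.012, mean -0.022, test up), reported Twist1 targets (median -0.021, mean 0.092, test up), p53 response (median -0.013, mean 0.14, test up), hypoxia and glycolysis (median -0.076, mean 0.26, test up), stem and mammary lineage markers (median -0.079, mean 0.0063, test down), fibroblast markers (median -0.0061, mean 0.24, test up) and endothelial markers (median -0.065, mean 0.19, test up), none of them called.

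Against parental cells the 3 re-expressing lines shared lower epithelial genes and higher cell cycle genes. Epithelial genes were lower for 20 of 31 members in the wild-type line (camera adjusted p = 3.0e-06, adjusted p = 0.087 with an estimated correlation), 22 in the S42A line (5.3e-11, held at 0.022) and 18 in the S42D line (6.0e-07, adjusted p = 0.098 with an estimated correlation). Cell cycle genes were higher for 37, 39 and 35 of 40 members (camera adjusted p = 5.2e-19, 1.1e-19 and 1.5e-16, and adjusted p = 0.087, 0.053 and 0.13 with an estimated correlation). Interferon genes were lower in the wild-type line for 23 of 34 (8.4e-06; adjusted p = 0.17 with an estimated correlation) and higher in the S42A line for 28 (5.1e-11; adjusted p = 0.053 with an estimated correlation). In the S42D line 11 were higher and 4 lower (0.024; adjusted p = 0.59 with an estimated correlation). TGF-beta components were lower for 17 of 34 in the wild-type line (0.0017; adjusted p = 0.17 with an estimated correlation) and 17 in the S42A line (0.00036; adjusted p = 0.084 with an estimated correlation). In the S42D line 14 were higher and 8 lower (0.25). Cholesterol synthesis genes were higher for 17 of 20 members in the wild-type line (9.3e-07; adjusted p = 0.17 with an estimated correlation) and 16 in the S42A line (1.9e-07; adjusted p = 0.11 with an estimated correlation). In the S42D line 6 were higher and 10 lower (0.44).

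The receptor chain gene Csf2rb was among the largest rises in all 3 lines, by 4.13 ± 0.098, 4.08 ± 0.098 and 5.27 ± 0.098 log2. In the wild-type line Atp13a4 (4.30 ± 0.094) and Dpt (3.89 ± 0.12) rose and Calcrl (-5.48 ± 0.084), Itga8 (-4.40 ± 0.069) and Spry1 (-4.40 ± 0.057) fell. In the S42A line Ppargc1a (5.74 ± 0.11) and Dpt (4.04 ± 0.12) rose and Hsd17b11 (-5.58 ± 0.098), Aldoc (-5.23 ± 0.079) and Jmjd8 (-4.54 ± 0.099) fell. In the S42D line Cd53 (5.33 ± 0.093) and Cdh5 (5.01 ± 0.087) rose and Sfrp1 (-4.19 ± 0.081), Trp53i11 (-4.18 ± 0.098) and Cxcl15 (-4.06 ± 0.095) fell. Fn1 fell in all 3 lines (-0.23, -0.51 and -0.16), in the wild-type and S42D lines not with median centring (-0.10 and -0.078, not called). Vim (0.070, 0.0096 and 0.025), Cdh2 (-0.11, 0.0083 and -0.081) and Snai2 (-0.10, -0.048 and -0.097) were not called. In the wild-type line Vim was called higher with median centring (0.19), quantile normalization (0.12), trend and robust settings or the dimmest genes left out, and lower with the neighbour correction (-0.39); Cdh2 was called lower with array weights. The fall of Fn1 in S42D was not called with the neighbour correction (-0.039). In the wild-type line 9778 genes were called (4984 higher, 4794 lower), in the S42A line 8036 (4512 and 3524) and in the S42D line 7378 (3944 and 3434). The split depends on the scaling, with 51.0%, 56.1% and 53.5% of calls higher, against 71.6%, 72.8% and 73.0% with median centring. Median centring moved the median of all genes in the wild-type line from -0.050 to 0.074.

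Camera with its preset correlation called reported Twist1 targets, PI3K-Akt components, p53 response genes and stem and mammary lineage markers in no comparison. Other settings called the PI3K-Akt and p53 lists in some comparisons against Tw1KD, as given there. On depletion fry called the Twist1 target (adjusted p = 4.9e-08), p53 (0.00030) and lineage lists (2.8e-05), not PI3K-Akt (0.81). On depletion reported Twist1 targets gave 3 higher (Bmi1, Cdh1, Foxa1) and 7 lower of 18, 10 adjusted within the list, camera adjusted p = 0.24, and among them the luminal factor gene Foxa1 (1.56 ± 0.083) rose and the matrix gene Sparc (-1.06 ± 0.033) fell. PI3K-Akt components gave 12 higher and 13 lower of 38, 25 adjusted within the list, camera adjusted p = 0.86, with Erbb3 (0.94 ± 0.086) higher and Irs1 (-1.13 ± 0.061) lower. The p53 response gave 11 higher and 6 lower of 26, 18 adjusted within the list, camera adjusted p = 0.25, and lineage markers 3 higher (Bmi1, Foxa1, Procr) and 6 lower of 28, 9 adjusted within the list, camera adjusted p = 0.25, with the milk protein gene Csn3 (-1.39 ± 0.045) lower. In no comparison did camera call a list for cell types that a carcinoma culture would not hold. Fibroblast markers gave 2 higher (Fbln1, Fbln2) and 4 lower (Dcn, Pdgfra, Pdgfrb, Pi16) of 16, 6 adjusted within the list, camera adjusted p = 0.51. Leukocyte markers gave 2 higher (Cd14, Cd68) and 0 lower of 17, 2 adjusted within the list, camera adjusted p = 0.51, with a rise of Cd68 (1.88 ± 0.048) and Cd14 (0.76 ± 0.10). Endothelial markers gave 1 higher (Cdh5) and 1 lower (Eng) of 14, 2 adjusted within the list, camera adjusted p = 0.95, where the rise of Cdh5 was not called with the neighbour correction (0.20) or only these lines fitted. In the S42D line against Tw1KD, fibroblast markers gave 5 higher (Dcn, Dpt, Fbln2, Pdgfra, Pdgfrb) and 1 lower (Fbln1) of 16, 6 adjusted within the list, camera adjusted p = 0.17 and endothelial markers 2 higher (Cdh5, Eng) and 5 lower (Egfl7, Emcn, Esam, Plvap, Tie1) of 14, 7 adjusted within the list, camera adjusted p = 0.93, with Cdh5 and Pdgfrb among the large rises. Housekeeping genes gave 2 higher (Eef2, Hprt) and 2 lower (Gusb, Tbp) of 10, 5 adjusted within the list, camera adjusted p = 0.51 on depletion, where Hprt (0.51 ± 0.070) rose and Gusb (-0.39 ± 0.041) fell. Eef2 was not called there without parental replicate 1 or 2 or Tw1KD replicate 3 (0.10, 0.10 and 0.10), nor with quantile normalization (0.078), the neighbour correction (0.077) or only these lines fitted, and Tbp not with the neighbour correction (-0.11). In the wild-type line against Tw1KD, housekeeping genes gave 7 higher and 1 lower (Eef2) of 10, 8 adjusted within the list, camera adjusted p = 0.12.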

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

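The tests of neighbouring genes, leukocyte markers, collagens, genes that went opposite ways from Tw1KD and the Twist1 level for the interferon and epithelial genes were chosen only after the results were seen, as was the neighbour correction; the remaining tests were written before their values were computed. Between pairs of re-expressing lines, many genes went opposite ways against Tw1KD and also differed in the direct comparison. They numbered 927 for wild-type Twist1 and S42A, 1448 for wild-type Twist1 and S42D, and 744 for S42A and S42D. Adhesion and integrin genes moved opposite ways in the wild-type and S42D lines, with a median difference of 0.27 log2 (camera adjusted p = 1.5e-05, adjusted p = 0.076 with an estimated correlation). Against Tw1KD these calls too were lost, at adjusted p = 0.38 and 0.23 with an estimated correlation. Interferon response genes did so in the wild-type and S42A lines, with a median difference of 1.31 (held at adjusted p = 0.010 with an estimated correlation; 0.11 and 0.069 against Tw1KD). Among the 11799 probe sets without a gene symbol, which the comparisons leave out, 519 were called higher and 412 lower in Tw1KD than in parental cells.

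The first pattern weighed is the 7978 genes that differed between the S42A and wild-type lines. Differences of genes 20 places apart on a chromosome correlated at 0.188, above the highest of 100 shuffled orders (0.0282), and 23 runs of genes shifted together, among them 198 genes from 4930527J03Rik to Marchf4 with a median of -0.59, both ends chosen after their values were seen. Blocks of this kind are consistent with copy number differences between the lines, which the arrays do not measure, but they do not account for most of the larger differences, since 67.6% of the genes called at least 1.5-fold kept that call after the neighbour correction. S42A was called beyond both other lines at 26.6% of responsive genes (2899 of 10914), where the Twist1 level cannot be told apart from other causes, because whether the probe set reads the introduced transcripts is not known and the order of the lines in Twist1 is open. At 11.6% of the called genes the wild-type and S42A lines went opposite ways from Tw1KD, which carries no introduced Twist1. Genes selected for this cannot test a steady effect of the Twist1 level alone. That effect, one of position 42 and separate histories of the lines remain open, since each construct is 1 line.

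The second pattern is the higher interferon response genes in the S42A line than in the wild-type line. Leukocytes in the culture are argued against, because the 75th percentile of their markers (0.187) lay below the 25th percentile of the interferon genes (0.734) although 3 of 17 markers were called higher (Cd68, Csf1r, Lyz2) and 1 lower (Cd14). Copy number of blocks with interferon genes is argued against as the main cause, since the median was 1.23 after the neighbour correction and 1.31 before it. A steady effect of the Twist1 level alone would move both lines the same way from Tw1KD, but the list medians lay at -0.58 in the wild-type line and 0.66 in the S42A line. The list was flagged because it went opposite ways from Tw1KD in these lines, so the medians cannot test that effect. The Twist1 level, an effect of position 42 and separate histories of the lines stay open, and no table tests them.

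The last pattern is the lower epithelial genes in all 3 re-expressing lines than in parental cells, a list call that held with an estimated correlation only for S42A (adjusted p = 0.087, 0.022 and 0.098 for wild-type, S42A and S42D). Fibroblasts in the cultures are argued against, because Col1a1, Col1a2 and Col3a1 were called higher in 0 of 9 limma comparisons with parental cells and every difference was negative, the highest being -0.00814, although other fibroblast markers were called higher: Dpt, Fbln1 and Pi16 in the wild-type line, Dpt, Fbln1 and Postn in the S42A line and Dpt, Fbln1, Fbln2 and Pdgfrb in the S42D line. Copy number is argued against as the main cause, since the median over the lines was -0.411 after the neighbour correction and -0.439 before it. Whether the lines held more Twist1 than parental cells cannot be told apart from a lasting change in the lines: the highest Twist1 difference was -0.0342, but whether the probe set reads the introduced transcripts is not known.

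For each of the 10 comparisons, the 6 arrays can be divided into 3 and 3 in only 10 ways, too few for a share under 0.05. The real division gave 7242, 9566, 8470, 8646, 7978, 8630, 7205, 9778, 8036 and 7378 called genes in the order of the comparisons above, main ones first, and in each case 1 of the 10 divisions, the real one, gave as many. The highest of the other divisions gave 88 for Tw1KD against parental cells and 0 by limma for the remaining 9. At an unadjusted p under 0.05 the highest were 3379, 1821, 2619, 1945, 1274, 775, 1360, 1184, 1673 and 1474.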

How the results depend on the processing

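Only the neighbour correction was added after the data were seen. The counts of called genes and of reversed genes stayed within 1.5 times their value under every alternative in which they were counted, except the 1.5-fold minimum. Reversed genes were not counted with the neighbour correction or with fits on the 2 lines alone. The 1.5-fold minimum by its construction leaves fewer genes: 1589, 2808, 2481, 2385, 1768, 2666, 1584, 2719, 2010 and 1503 for the comparisons in the order used above, and 726, 848 and 966 reversed genes for wild-type, S42A and S42D. Leaving out 1 array at a time gave 6618 to 7445, 8539 to 10179, 7838 to 8458, 7923 to 8881, 7025 to 7775, 7967 to 8284, 6525 to 6805, 8593 to 9917, 7258 to 8122 and 6222 to 7416 called genes in the same order, and 3684 to 3939, 4013 to 4379 and 4572 to 4949 reversed genes. The Twist1 difference ranged over -1.75 to -1.63, 0.91 to 1.07, 1.30 to 1.42, 1.59 to 1.71, 0.29 to 0.45, 0.58 to 0.75, 0.24 to 0.34, -0.78 to -0.62, -0.38 to -0.28 and -0.067 to -0.016 on leaving out 1 array, and the neighbour correction gave -1.90, 1.17, 1.39, 1.79, 0.22, 0.62, 0.40, -0.73, -0.51 and -0.11; the call, or the lack of one, was the same in every setting, but for S42D against parental cells, not called, median centring turned the sign (to 0.046). With the replicate number as a replicate block the counts were 7046, 9407, 8319, 8544, 7755, 8468, 7028, 9642, 7892 and 7129; the numbers do not pair the arrays, since 6 of 15 arrays had their closest partner in residuals under the same number.

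The neighbour correction turned the sign of 12 of 679 named results and ended 20 further named calls. Vim became -0.39 in wild-type Twist1 against Tw1KD, 0.43 in S42A and 0.41 in S42D against wild-type, and -0.39 in wild-type against parental cells. Fn1 became 0.13 and Mcm5 0.10 in S42D against Tw1KD, and Skil -0.0092 and Ywhaz 0.12 in S42A against wild-type. Ccnd1 became -0.018 and Ccna2 -0.23 in S42D against wild-type, and Mcm4 -0.012 and Asns 0.18 in S42D against S42A. Vim and Fn1 lay near the array maxima, so their corrected values mostly carry the shift of neighbours; its cause was not tested. Fry, which tests a list on its own and not against other genes, called 6 lists in the direction opposite to camera, which had not called them. Their medians were 0.069 for TGF-beta response genes on depletion and -0.039 and 0.036 for reported Twist1 targets in wild-type and S42A against Tw1KD. TGF-beta components gave -0.023 and 0.0062 in S42A against Tw1KD and wild-type, and cytokines 0.0054 in S42A against Tw1KD. Of 119 list results, an estimated correlation ended most calls (38), and fry added 47. Among lists, leaving out 1 array added 10 calls and ended 8 of 714 results; among named genes it added 2 and ended 52 of 4074. Median centring ended 15 named calls and quantile normalization 5; the mean of probe sets ended none. Background signals limit the folds of dim genes, and leaving out the dimmest genes ended 3 list calls.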

Other observations

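The gene sets described here were chosen after the values were seen, and no test of them was planned. All 4 derived lines differed from parental cells in the same direction at 1535 genes, 959 higher and 576 lower. Independent lists would share 68, and unchanged lines, with few calls to share, gave 0. Log2 levels in Tw1KD, wild-type, S42A and S42D cells follow the parental level for each example. Higher in all were the immune checkpoint gene Havcr2 (6.38 in parental cells, 9.29, 9.59, 8.75 and 10.06), the phosphatase gene Dusp9 (8.58 in parental cells, 10.11, 10.47, 10.80 and 9.90) and the lysosomal gene Cd68 (8.50 in parental cells, 10.38, 9.80, 10.27 and 10.71). Lower in all were the Wnt antagonist Sfrp1 (9.36 in parental cells, 5.23, 5.15, 5.31 and 5.16), the transcription factor gene Osr1 (10.42 in parental cells, 7.03, 7.55, 6.50 and 7.02), the epithelial splicing gene Esrp1 (7.84 in parental cells, 5.20, 5.05, 5.22 and 5.15) and the Wnt-induced matrix gene Ccn4 (9.73 in parental cells, 7.41, 7.66, 7.68 and 7.78). Part of the shared calls can come from the parental arrays all contrasts use or from descent from Tw1KD, so 68 is no fair reference. Whether parental cells received the same drugs is not stated.

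Runs of neighbouring genes that shifted together were present in every comparison, with correlations at 20 places between 0.0713 (Tw1KD against parental cells) and 0.188 (S42A against wild-type), each above its 100 shuffled orders. In the S42D line against parental cells, 205 genes from Pigx to A630089N07Rik had a median of 0.65, and 83.4% of them shared its sign. Runs held 382 genes in the wild-type line, 620 in the S42A line and 950 in the S42D line against parental cells, of 13330 genes in order.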
